A study of Zea mays with 6 samples.

How the data were processed

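Gene expression was measured by RNA sequencing in leaves of the maize inbred line KN5585 in 6 libraries, 3 from control plants and 3 from transgenic plants made to synthesise poly-γ-glutamic acid, a polymer of glutamate. Per the labels, seedlings at the 3-leaf stage went without water for 5 days, until the soil held 9.8% water, and libraries were made from 1.3 µg of total RNA with a SMARTER mRNA kit. Groups and replicate numbers were taken from the labels. The labels do not say that the 3 libraries of a group came from separate plants, so the p-values measure only the spread between these samples, which may be technical. Plants with normal watering were not analysed here, so that no effect of drought itself can be read from these values. Both groups carried the stress.

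Each deposited file holds the FPKM values (fragments scaled by gene length and by the number of mapped fragments) of 1 library, calculated by the authors and rounded to 2 decimals, for the same 33953 features. The aligner, the counting method, the annotation and the use of strand are not given in the sources used here. The submitters' processing notes name the genome builds GRCm38 and mm10, which are mouse builds and do not match the maize feature IDs in the files. No genome build could therefore be taken as known, and no coordinates or gene lengths are given. The features fall into 33702 nuclear, 104 plastid and 147 mitochondrial IDs. In the reference gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, 0 of the nuclear IDs and all plastid and mitochondrial IDs had a match, by locus tag. The table was used only for symbols, gene order and overlaps between genes. Nuclear genes are therefore reported by number, with 2 IDs in each direction. No feature carried the name of the transgene, which was not analysed here.

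Counts of reads were not analysed here. FPKM summed to between 1208094 and 1238707 per library. Steps between the low values of the same gene gave the depth of each library relative to control replicate 1, which lay between 0.961 and 1.03, a span of 1.07-fold. On 3 simulated pairs of libraries this estimate was off by at most 0.001. Both libraries of a simulated pair had the same expression profile, so the error between libraries of different genotypes is not known. The absolute depth is unknown, so no counting intervals are given. An FPKM of 0 means only that a gene is listed at 0.

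Features with a mean FPKM of at least 1 over the 6 libraries were tested, 22200 in all (22077 nuclear, 74 plastid and 49 mitochondrial), and 11753 were left out, of which 2035 were listed at 0 in all libraries. The 2 groups were compared on log2(FPKM + 1) with limma (version 3.58.1 in R 4.3.3; lmFit, and eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are transgenic minus control on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Values are given as mean ± SD over 3 libraries unless an SE is named. Among 22200 simulated features of which 200 were changed, this test recovered 8% of those changed by 0.5 on the log2 scale, 62% of those changed by 1, 90% of those changed by 2 and 52% of those changed by -1, and 3.64% of its calls were false. In the data themselves 72.95% of tested features passed. With as few changed features as in the simulation the adjustment is stricter, so the simulated shares do not describe the comparison made here.

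Lists of nuclear genes for drought, hormone, photosynthesis and other functions, and families of genes with the same product, had been fixed before the data were examined. They could not be tested, since the nuclear IDs had no symbols or products. In their place, plastid and mitochondrial genes were grouped by symbol into protein complexes after the values had been seen. Within these groups a second copy with the same FPKM in every library (12 tested features) was counted once, and features of the mitochondrion that are marked as plastid-derived were left out. Reads of such copies cannot be told apart. Groups with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over the groups. On simulated data, a shifted set of 15 members ranked 1 among 201 sets, and 0 of the unshifted sets passed. The simulated genes varied independently of each other and few were changed, so this says nothing about whether the preset correlation holds for these groups.

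The genes named were chosen by a rule fixed before the data were examined. It takes the 8 higher and the 8 lower genes with a named product that had the largest log2 fold change among those past the threshold with no overlap between the groups, and up to 3 members of each group with the lowest p among those past the threshold. Open reading frames with no known product, second copies and plastid-derived features were not taken. The organelle groups stand in for the fixed lists in this rule. A set of nuclear genes named in the rule (dehydrin 1 and enzymes of photosynthesis, among others) had no matched ID. A gene named outside the rule is said to be so. One gene that the rule takes is not reported here.

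Alternatives were 3 other scalings (median-of-ratios size factors, quantile normalization, and a total of 1000000 per library), a pseudocount of 0.1, no filter, a minimum mean FPKM of 5, eBayes without trend, weights per library, the replicate number as a block, a fold threshold of 1 on the log2 scale, and leaving out each library in turn. For the groups, camera with an estimated correlation and fry were added. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.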

Results

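Leaf transcripts of control and transgenic KN5585 maize were compared after 5 days without water. The transgenic plants had been made to synthesise poly-γ-glutamic acid, and the comparison asks which transcripts differ between the genotypes when both are under drought. Each genotype had 3 libraries. The deposited FPKM covered 33953 features, of which between 26501 and 27689 were above 0 in a library. Estimated relative depth differed by at most 1.07-fold between libraries, and the absolute depth is unknown. Across tested genes, log2 values of libraries of the same genotype correlated with a Pearson r of 0.972 to 0.976 in control and of 0.986 to 0.989 in transgenic plants, and libraries of different genotypes with an r of 0.693 to 0.708. Genes are not independent replicates, so these coefficients carry no p-value. Symbols could be assigned to plastid and mitochondrial genes, whereas nuclear genes are given by number.

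In transgenic leaves, FPKM of plastid features moved mostly up and those of mitochondrial features mostly down. All libraries were made with an mRNA kit, and plastid features held at most 0.57% and mitochondrial features at most 0.198% of FPKM in any library. A difference between the groups in the capture of organelle RNA was not tested and cannot be told apart from a change in transcripts. Of 19 plastid genes of ribosomal proteins, 17 rose, with rps14 going from 16.6 ± 6.41 to 272 ± 38.1 FPKM. The exception among the largest plastid changes was psbA, which encodes the D1 reaction centre protein of photosystem II and dropped from 159.7 ± 6.35 to 1.30 ± 0.778 FPKM (n = 3 per group). In the mitochondrion, 13 of 14 tested genes of the respiratory chain and ATP synthase fell, among them cox1, a core subunit of cytochrome c oxidase, from 19.6 ± 1.96 to 0.667 ± 0.211 FPKM. These shifts were part of a change that reached most of the transcriptome, since 16195 of 22200 tested features passed the threshold, 5996 higher and 10199 lower. In the set test of the main setting, 2 organelle groups passed upward and 0 downward, and 0 passed upward with an estimated correlation between genes.

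Of the features tested, 5996 were higher and 10199 lower in transgenic leaves (limma, Benjamini-Hochberg adjusted), and 6005 did not pass. At 2-fold or more the numbers were 3806 higher and 5712 lower, and at 8-fold or more 747 higher and 669 lower. The groups did not overlap for 16712 features, or 75.3%, where chance gives 10%. Calls were more frequent among abundant features, with 57.4% passing in the lowest, 74.5% in the middle and 87.0% in the highest of 3 equal classes of mean FPKM. The share of calls that were lower was 63.0% with FPKM as deposited, 48.5% after median-of-ratios scaling (7986 higher, 7533 lower) and 54.4% after quantile normalization (7185 higher, 8563 lower). The median log2 fold change of all tested features was -0.31 as deposited, 0.04 with median-of-ratios scaling and -0.09 with quantile normalization. Group medians below are therefore also given relative to the median of all tested features.

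**Figure D1:**
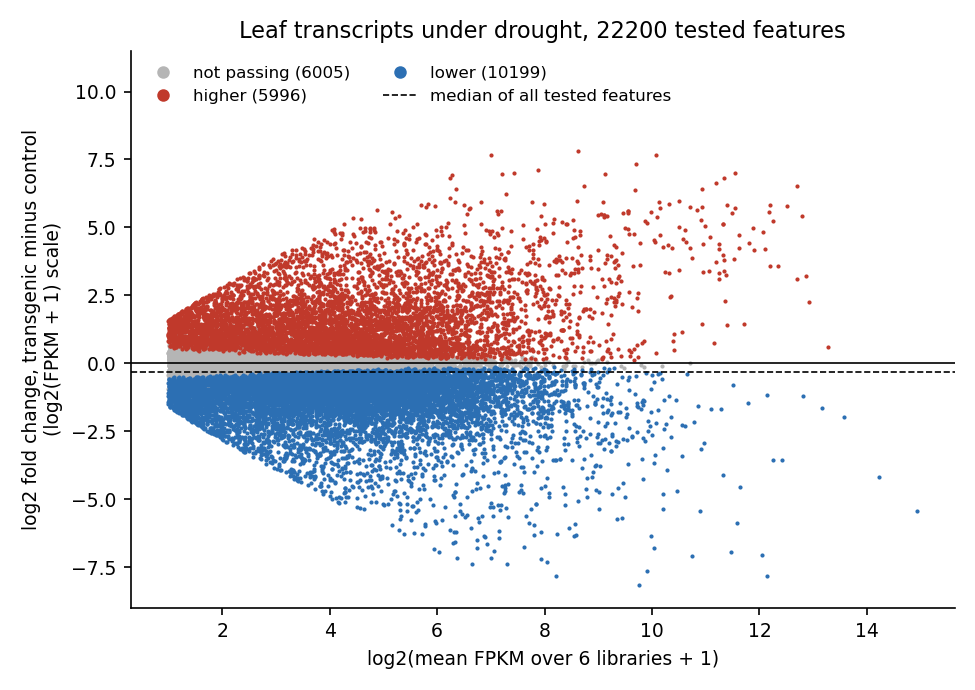
Log2 fold change (transgenic minus control, log2(FPKM + 1) scale) against log2 of the mean FPKM + 1 over 6 libraries for 22200 tested features, with 5996 higher in red, 10199 lower in blue and 6005 not passing in grey. The dashed line marks the median of all tested features, -0.31, which lies at 0.04 with median-of-ratios scaling.

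The most abundant transcripts were largely different ones in the 2 genotypes. Of the 100 most abundant features, 16 were shared between the groups. The nuclear transcript with the highest level in control leaves had 61332 ± 2476 FPKM there, 5.03% of the total, and 1415 ± 98.0 FPKM in transgenic leaves. The second went from 36195 ± 797 to 1971 ± 90.1 FPKM. The most abundant transcript of transgenic leaves had 13942 ± 600 FPKM there and 324 ± 29.2 FPKM in control leaves. These 3 transcripts were singled out after their values were seen. The 10 most abundant features held 14.8 to 15.5% of FPKM in control and 9.43 to 9.67% in transgenic libraries. By the fixed rule, the largest rises of nuclear genes were those of Zm00001d027291, from 2.56 ± 1.01 to 784 ± 32.7 FPKM, and Zm00001d019400, from 0.317 ± 0.548 to 254 ± 13.1 FPKM. The largest falls were those of Zm00001d025753, from 1729 ± 87.8 to 5.38 ± 2.37 FPKM, and Zm00001d003554, from 592 ± 13.1 to 1.75 ± 1.04 FPKM. Their limma adjusted p lay between 1.75e-09 and 1.37e-08. Nothing more can be said of these nuclear genes here because their IDs had no match in the reference gene table. Of the nuclear genes tested, 5945 rose and 10161 fell.

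Of 66 plastid features counted once, 41 rose, 11 fell and 14 did not pass, with a median log2 fold change of 1.07, which is 1.38 above the median of all tested features. The plastid share of FPKM, copies included, was between 0.193% and 0.221% in control and between 0.496% and 0.570% in transgenic libraries, all of which were made with an mRNA kit. The rise that took in the most genes, 17 of 19, was that of the ribosomal protein genes, which serve translation within the plastid. Their median log2 fold change was 2.12, or 2.43 relative to all tested features, and the group passed its set test (camera, adjusted p = 1.1e-06), but not with an estimated correlation between genes (adjusted p = 0.301 with an estimated correlation). Besides rps14 (ZemaCp021, log2 fold change 4.01, SE 0.22), the larger rises included those of rpl14 (ZemaCp059) from 6.99 ± 1.23 to 59.8 ± 2.90 FPKM, rps4 (ZemaCp026) from 12.8 ± 3.66 to 82.4 ± 7.5 FPKM and rps3 (ZemaCp061) from 78.8 ± 12 to 405 ± 40.5 FPKM. One member, rps16, fell by 1.17, and rpl20, at 0.31, did not pass; both were named after their values were seen. Of the genes of the plastid-encoded RNA polymerase, rpoA (ZemaCp054) rose by 1.63, and rpoC1 (ZemaCp014) fell by 0.72 from a mean of 1.54 FPKM, a call that was lost without transgenic replicate 2 (limma, adjusted p = 0.0812).

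Genes of the photosynthetic complexes did not move alike. Relative to the median of all tested features, the group medians were 2.32 for photosystem I, 0.07 for photosystem II, 0.82 for the cytochrome b6f complex, 0.98 for the NDH complex and 2.37 for the plastid ATP synthase. Of 5 photosystem I genes, 4 rose and 1 fell, with a median of 2.02 (camera, adjusted p = 0.0628), which did not pass. The group passed with median-of-ratios scaling (adjusted p = 0.0469), with no filter (adjusted p = 0.0479), and without control replicate 3 or transgenic replicate 3 (adjusted p = 0.0406 and 0.0433). It did not pass with an estimated correlation between genes (adjusted p = 0.301 with an estimated correlation), and fry, which does not compare the group with other genes, gave an adjusted p of 0.000299. The photosystem I core gene psaA (ZemaCp023) went from 4.20 ± 0.546 to 39.7 ± 5.07 FPKM, psaB (ZemaCp022) from 1.01 ± 0.282 to 5.62 ± 1.09 FPKM and psaJ (ZemaCp043) from 9.51 ± 6.57 to 37.1 ± 8.78 FPKM. The gene that fell, psaC, which is named after its value was seen, changed by -0.22, a call that was lost with median-of-ratios scaling, quantile normalization or eBayes without trend, and without control replicate 2 or any 1 of the transgenic replicates. Of 14 photosystem II genes, 3 rose, 5 fell and 6 did not pass. Their median was -0.24 and their mean -0.49, while the set test against all other genes gave an upward direction (camera, adjusted p = 0.758). Without that comparison the direction was downward (fry, adjusted p = 0.000624). The median of these genes turned to 0.08 with median-of-ratios scaling. The balance of calls turned too, with 5 higher and 3 lower under that scaling and 5 higher and 4 lower with quantile normalization. Against the mixed movement of this group, psbA (ZemaCp002) fell by 6.19 on the log2 scale (SE 0.24; limma, adjusted p = 3.89e-08). It lay between 153 and 166 FPKM in the control and between 0.41 and 1.85 FPKM in the transgenic libraries. The antenna protein gene psbC (ZemaCp008) fell by 1.67, from 41.0 ± 4.31 to 12.2 ± 0.679 FPKM, and it overlaps psbD in the reference gene table, so that part of its reads can belong to that gene. The small subunit gene psbK (ZemaCp005) rose by 0.91, from 53 ± 7.39 to 100.2 ± 5.85 FPKM.

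Of 6 genes of the cytochrome b6f complex, which links the photosystems, 3 rose, 2 fell and 1 did not pass (camera, adjusted p = 0.526). The largest fall was that of petD (ZemaCp053), by 2.06 from 45.7 ± 9.07 to 10.2 ± 2.25 FPKM, and petG (ZemaCp042) and petA (ZemaCp036) rose by 0.99 and 0.69. Of 6 tested genes of the NDH complex, which takes part in cyclic electron flow, 4 rose and 0 fell, with a median of 0.67 (camera, adjusted p = 0.0424; adjusted p = 0.343 with an estimated correlation). This call was also lost with quantile normalization (adjusted p = 0.0542) and without a variance trend (adjusted p = 0.0536). The most abundant members were ndhC (ZemaCp029), from 272 ± 15.9 to 935 ± 54.4 FPKM, ndhK (ZemaCp028), from 313 ± 16.5 to 848 ± 60.7 FPKM, and ndhJ (ZemaCp027), from 96.4 ± 6.54 to 159.6 ± 12.8 FPKM. Of 4 tested genes of the plastid ATP synthase, too few for the set test, 3 rose. With 5 tested genes the group passed upward with median-of-ratios scaling (camera, adjusted p = 0.0469) and with no filter (adjusted p = 0.0229). It also did so without control replicate 2, control replicate 3 or transgenic replicate 3 (camera, adjusted p = 0.0237, 0.0406 and 0.0169). The gene of the epsilon subunit, atpE (ZemaCp030), had the largest rise of all plastid genes, 4.93 (SE 0.30), from 0.843 ± 0.753 to 51.4 ± 3.15 FPKM. It was listed at 0 in 1 control library, and it overlaps atpB, which did not reach the minimum FPKM. The gene atpF (ZemaCp019) rose from 75.7 ± 8.86 to 536 ± 61.4 FPKM, and atpI (ZemaCp017) from 0.503 ± 0.153 to 2.78 ± 0.664 FPKM.

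**Figure D2:**
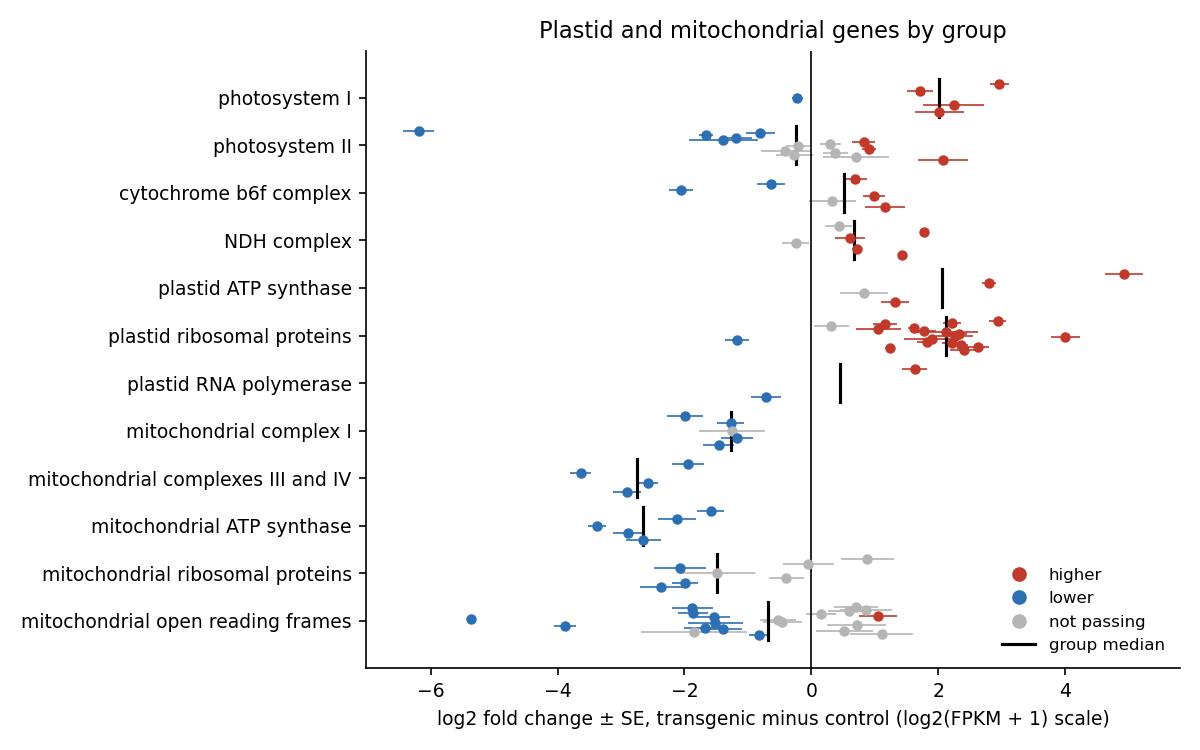
Log2 fold change (transgenic minus control, log2(FPKM + 1) scale) with SE of each tested plastid and mitochondrial gene, by group, with genes that rose in red, those that fell in blue, those that did not pass in grey and the group median as a black bar. Plastid ribosomal genes lie around a median of 2.12, mitochondrial ATP synthase genes around -2.65, and psbA stands apart at -6.19; the photosystem II median of -0.24 turns to 0.08 with median-of-ratios scaling.

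Of 41 mitochondrial features counted once and not marked as plastid-derived, 1 rose, 25 fell and 15 did not pass, with a median log2 fold change of -1.51, which is -1.20 relative to the median of all tested features. The number that rose depended on the scaling, as 5 open reading frames and 1 ribosomal protein gene rose with median-of-ratios scaling. Of 4 plastid-derived features of the mitochondrion, left out of these counts, 2 rose, 1 fell and 1 did not pass. The 4 genes of complexes III and IV all fell, with a median of -2.75. Besides cox1 (ZeamMp136), which fell by 3.63 (SE 0.17), cox3 (ZeamMp161) went from 12.9 ± 3.41 to 0.813 ± 0.170 FPKM and cox2 (ZeamMp179) from 13.0 ± 1.13 to 1.34 ± 0.251 FPKM. The 5 genes of ATP synthase, the enzyme that makes ATP from the proton gradient, all fell as well, with a median of -2.65, but the group did not pass its set test (camera, adjusted p = 0.0628). Among them atp6 (ZeamMp182) went from 36.5 ± 4.09 to 2.61 ± 0.363 FPKM, atp9 (ZeamMp108) from 29.4 ± 4.31 to 4.12 ± 2.15 FPKM and atp8 (ZeamMp081) from 11.6 ± 2.22 to 0.707 ± 0.412 FPKM. This group passed with median-of-ratios scaling (adjusted p = 0.0281), quantile normalization (adjusted p = 0.047), no filter (adjusted p = 0.0229), and without control replicate 3 or transgenic replicate 3 (adjusted p = 0.0406 and 0.0433). It did not pass with an estimated correlation (adjusted p = 0.301 with an estimated correlation), and fry gave an adjusted p of 3.56e-05. Of 5 genes of complex I, the entry point of the respiratory chain, 4 fell and 1 did not pass, with a median of -1.27 (camera, adjusted p = 0.243, and fry, adjusted p = 0.000319). Its members were at low levels, with nad3 (ZeamMp093) at 4.44 ± 1.66, nad9 (ZeamMp036) at 3.39 ± 0.885 and nad4 (ZeamMp032) at 2.09 ± 0.223 FPKM in control leaves. Their means in transgenic leaves were 0.357, 0.597 and 0.283 FPKM. Of 7 mitochondrial ribosomal protein genes, 3 fell and 4 did not pass (camera, adjusted p = 0.526, and fry, adjusted p = 0.000319). Those that fell were rps7 (ZeamMp159) by 2.37, rps12 (ZeamMp092) by 2.06 and rps2B (ZeamMp157), which overlaps orf261 in the reference gene table, by 1.99. Without control replicate 2, 5 of 6 tested ribosomal protein genes fell and 1 rose. Relative to the median of all tested features, the medians were -0.96 for complex I, -2.44 for complexes III and IV, -2.34 for ATP synthase and -1.18 for ribosomal proteins. The median of each of these groups, ribosomal proteins included, was below 0 under each of the 4 scalings.

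**Figure D3:**
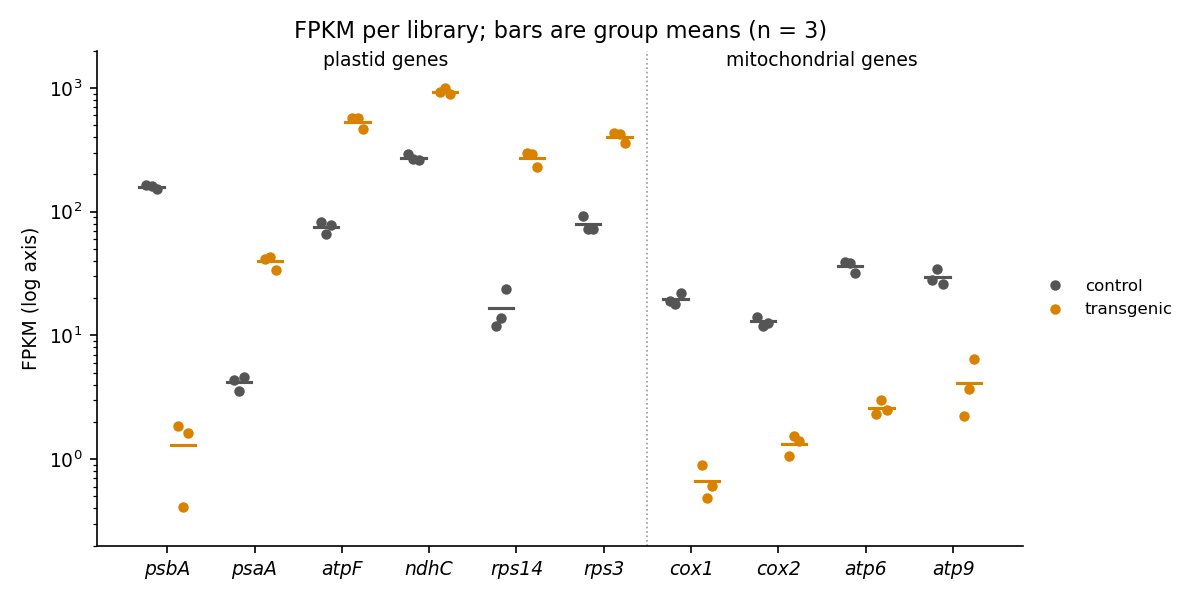
FPKM on a log axis in each of the 3 control (grey) and 3 transgenic (orange) libraries for 6 plastid and 4 mitochondrial genes, with bars at the group means. The groups do not overlap for any of the 10 genes shown, which the rule for naming required of all but ndhC. The same held for 75.3% of all tested features. The gene psbA lies between 153 and 166 in control and between 0.41 and 1.85 in transgenic libraries.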

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

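The organelle groups and all their settings were chosen after the data were seen; the other alternatives were fixed before. The counts of 5996 higher and 10199 lower genes stayed within 1.5 times of these values under all scalings, pseudocounts, filters, variance models and left-out libraries, with 5358 to 5988 higher and 9593 to 9998 lower genes when 1 library was left out. Requiring a 2-fold change gave 3806 and 5712, since fewer genes can pass. Median-of-ratios scaling kept 13557 calls, 13529 of them in the same direction. With the replicate number as a block, 5935 genes were higher and 10087 lower, and psaC lost its call. Deviations of libraries with the same number correlated at 0.006, -0.001 and 0.015, so the numbers were not taken as pairs. Of 557 values of the 38 genes taken by the rule under alternatives, 556 kept their direction and side of the threshold. The other 1, rpoC1, lost its call without transgenic replicate 2 (log2 fold change -0.63). These genes were picked for large changes or low p in the same libraries, so this says little about other calls. The fold threshold was not among these settings, and rpoC1, petA, ndhJ, psbK and petG changed by less than 1. A gene below the minimum mean FPKM of a setting had no value there. This was so for rpoC1 with median-of-ratios scaling and for nad4 with a total of 1000000 per library, among others. The number of organelle groups past the set test, 2 higher and 0 lower, depended on the setting. It was 4 higher and 1 lower with median-of-ratios scaling and with no filter, 1 higher and 1 lower with quantile normalization, and 1 higher with a minimum mean FPKM of 5 and with eBayes without trend. With an estimated correlation 0 groups were higher, and with fry, which does not compare a group with other genes, 3 were higher and 5 lower. Leaving out 1 library gave 2 to 4 higher and 0 to 1 lower, with 4 and 1 without control replicate 3 and without transgenic replicate 3. The minimum mean FPKM of 5 left the NDH complex too few members. The plastid ATP synthase had too few in the main setting. It had 5, and was among the higher groups, with median-of-ratios scaling and with no filter. The same held without control replicate 2, control replicate 3 or transgenic replicate 3. Other causes were not tested. The fixed lists and product families were not run, since no nuclear ID had a symbol or product, and the alternative with 1 member per product name could not be run either. Depth limits are unknown, because FPKM carry no counts, and genes near 1 FPKM have understated changes.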

Other observations

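In this part the limma calls and their scaling and left-out-library alternatives were planned, and the permutation tests, the splits of the libraries, the shares of abundant features, the comparisons of organelle medians and the ID windows were chosen after the results they measure had been seen. Of 7 tested plastid genes outside the groups of the report, 5 rose, 1 fell and 1 did not pass. The genes named in this paragraph were picked after their values were seen. The gene of the protease subunit clpP went from 14.8 ± 1.32 to 64.5 ± 3.63 FPKM, those of the photosystem I assembly factors ycf3 and ycf4 from 15.7 ± 4.38 to 66.4 ± 2.47 and from 11.6 ± 4.43 to 29.1 ± 2.19 FPKM, and that of the translation initiation factor infA from 205.7 ± 27.7 to 362 ± 48.2 FPKM (n = 3 per group). The maturase gene matK, which overlaps trnK in the reference gene table, fell by 0.67 (limma, adjusted p = 0.0249), a call that was lost with median-of-ratios scaling (adjusted p = 0.111) and without control replicate 1, transgenic replicate 1 or transgenic replicate 3 (adjusted p = 0.0775, 0.0741 and 0.0798). The gene ccsA, with a log2 fold change of 0.65, did not pass (adjusted p = 0.0553) but rose with median-of-ratios scaling (adjusted p = 0.0111), with quantile normalization (adjusted p = 0.0223) and without control replicate 1 (adjusted p = 0.00251). Among 20 tested open reading frames of the mitochondrion with no known product, 1 rose, 9 fell and 10 did not pass. Of 19 tested with median-of-ratios scaling 5 rose and 8 fell, and of 19 tested without control replicate 1, 5 rose and 10 fell. The most abundant of these open reading frames, orf111-b, had 1011 ± 24.1 FPKM in control and 23.7 ± 2.15 FPKM in transgenic leaves, the largest fall of a mitochondrial feature. In the reference gene table it overlaps rrn18, the gene of the small subunit ribosomal RNA of the mitochondrion, so its FPKM can hold reads of that RNA. Next to cox1 in that table, orf147-b fell by 3.88 on the log2 scale, where cox1 fell by 3.63.

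Within the plastid, 23 tested genes of gene expression (ribosomal proteins, polymerase, matK and infA) had a median log2 fold change of 1.82 and 35 genes of photosynthesis one of 0.69. The difference of 1.13 had a two-sided permutation p of 0.0086. The log2 fold changes of 62 pairs of neighbouring plastid genes correlated across genes with an r of 0.42 (one-sided permutation p = 0.0001), which is in line with transcription or reads shared along the plastid genome. As neighbours move together and several ribosomal genes lie side by side, the first p is too small by an unknown amount. A hypothesis is that the plastid gene expression machinery rose more than photosynthesis genes in the transgenic leaves, but position along the genome may account for part of it.

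Most tested genes passed the test between the genotypes. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 16195 genes, and the highest of the others gave 0, but these mix the genotypes, whose difference then adds to the spread, and 10 splits cannot give a share below 0.1. Scaling does not account for the number, since the lowest count under the 3 other scalings was 15519. The labels name no library or sequencing batch, so none could be checked. A difference between the plants themselves, from the transgene or from the state of the leaves at sampling, stays open and was not tested. The genotype label reads only control or transgenic, so the transgene cannot be told apart from any other difference between the 2 groups of plants.

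More genes fell than rose with FPKM as deposited, with a median log2 fold change of -0.31. The 19 features among the 10 most abundant of either group held 15.4 to 16.1% of FPKM in control and 10.9 to 11.3% in transgenic libraries, which would move the other features up by 0.08 on the log2 scale, against the direction of the excess. The 184 features among the 100 most abundant of either group held 31.5 to 32.5% and 37.9 to 39.3%, a change that leaves the others at -0.14 (-0.17 to -0.12 over the pairs of libraries). This could account for part of the median of -0.31, and what makes up the rest stays open. The even split after median-of-ratios scaling says nothing about the source, since that scaling centres the typical gene, and a drop of transcripts per cell cannot be read from relative values.

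Plastid and mitochondrial transcripts moved apart. A gain of plastid RNA or DNA alike for all plastid genes would move them 1 way, whereas at least 5 of 56 plastid genes fell, and at least 35 rose, under each of 4 scalings. A general gain with falls of single plastid genes stays open. A loss alike for all mitochondrial features would shift them by the same amount, but over 14 features with a mean FPKM of at least 5 the SD of the log2 fold change (pseudocount 0.1) was 1.58, against a median SE of 0.30, with a range from -5.41 to 0.64. The ends of this range are orf111-b and orf342, which overlap rrn18 and orf396 in the reference gene table. Part of the spread can therefore come from reads of those features. As 13 of the 14 lay below 0, a general loss with further changes of single features stays open. Without features that have a copy, the plastid median was 0.95 and the mitochondrial one -1.53, so reads shared between such copies do not account for the shift, while nuclear copies of organelle DNA and the capture of organelle RNA by the mRNA kit remain open, as does a response of the organelles to the transgene.

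Some nuclear genes were listed at 0 in all libraries of 1 genotype. With at least 5 FPKM in every control library, 18 genes were listed at 0 in every transgenic library, and 12 the other way round. Another 37 and 20 genes had a mean above 0 but no more than 0.1 FPKM in the other genotype. A hypothesis was a chromosome block of other origin in 1 genotype, which would place many of these 30 genes close together. The most within 500 consecutive ID numbers was 4, no more than the 4 that 95% of 10000 random draws stayed within. This argues against a single block that holds many of these genes, while a block with only a few of them could go unseen. Scattered differences between the plants may remain. Across 10757 pairs of nuclear genes with consecutive ID numbers, log2 fold changes correlated with an r of 0.125 (one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Shared regulation, tandem copies and shared reads are candidate sources of this weak relation and were not separated.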
